A study of Bos taurus with 12 samples.

How the data were processed

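Endometrial biopsies of Simmental heifers, taken at day 7 and day 14 of the cycle before embryo transfer, were profiled on Affymetrix bovine 3' expression arrays. The labels place the arrays in 4 groups by day and by what followed the transfer: CD (pregnancy that ended in delivery of a calf) and NP (no pregnancy, with a return to heat). Each group has 3 arrays, and each array holds RNA of a pool, per the labels' protocols. The number of heifers in a pool and which heifers entered it are not given in the sources used here. The p-values below therefore measure the spread between these pools. The pool number was taken from the sample titles, and in CDd14 a title whose name and replicate number differ was read by its replicate number.

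The authors deposited log2 values made with GCRMA, which corrects the background, normalizes between arrays and summarises the probes of each probe set. GCRMA and limma are named in the submitters' processing notes, and versions are not given in the sources used here. GCRMA pulls dim probe sets toward a common floor, so a fold change measured from a dim level depends on that floor. The table holds 24128 probe sets with values from 0.40 to 16.01 on the log2 scale. No detection calls were used here. Before the comparisons, 112 AFFX control probe sets were left out. A probe set was then kept when its log2 value was above 4 on at least 3 of the 12 arrays, which kept 13449 of 24016 probe sets (56.0%). In the annotation, 8239 of the kept probe sets carry 1 gene symbol, 59 carry several and 5151 are not listed and so are unnamed here. Symbols were checked through gene identifiers, which matched 13283 of the annotated probe sets with 1 symbol and left 35 unmatched. This changed 0 symbols, so older names may remain. No genome coordinates were used. The number of arrays limits the precision.

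All comparisons were made with limma 3.58.1 in R 4.3.3: a linear model with 4 group means over the 12 arrays (8 residual degrees of freedom), contrasts, empirical Bayes moderation with default settings (2.13 prior degrees of freedom) and Benjamini-Hochberg adjustment over the 13449 probe sets. The threshold was an adjusted p under 0.05, two-sided. The 5 contrasts were CD minus NP at day 7, CD minus NP at day 14, day 14 minus day 7 in CD, day 14 minus day 7 in NP, and the difference of the day effect between CD and NP. Genes are represented by their kept probe set with the highest mean over the 12 arrays, which gives 6781 genes, 1189 of them with over 1 kept probe set. Unless probe sets are named, counts within a list are of genes, with p adjusted over all probe sets.

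The lists of genes, the filter, the contrasts, the alternatives and the rule for the genes named were set before the data were examined. The rule takes, for each pairwise contrast, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups do not overlap. Where under 5 genes pass, the 5 with the smallest p are added as values. From each list it takes up to 4 members past the threshold with the smallest p, and up to 3 members with the smallest p of a list that was called. It always takes PGR, ESR1, OXTR, MSTN, DKK1, SERPINA14, LPL, ISG15 and MX1 where measured. For the difference of the day effects it takes the 5 genes with the smallest p where none pass. For length the text leaves out some list members and, at day 7, some of the genes with the largest changes.

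Of 27 gene lists for uterine functions and cell types, 22 had at least 5 measured genes. They were tested in each contrast with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 110 tests. Camera with an estimated correlation and fry, which tests whether a list moves on balance in 1 direction, were run beside it. Camera at the preset correlation called 40 of the 110 tests, camera with an estimated correlation called 0 (smallest adjusted p = 0.727, with 6 at an unadjusted p under 0.05) and fry called 1, the growth factors between days in CD. Where a list is said below to have been higher or lower, this rests on the preset correlation. Except between days in NP, other splits of the arrays called as many lists in each contrast, as given near the end.

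The scripts were tested on simulated data with 200 changed probe sets among 13449, in 1 simulation per contrast and fold. At a fold of 4, 89.0% were recovered for CD minus NP at day 7, 84.0% for CD minus NP at day 14, 86.5% for the day effect in CD, 89.0% for the day effect in NP and 73.0% for the difference of the day effects. At a fold of 2 the shares were 46.5%, 44.5%, 49.0%, 45.5% and 12.0% in that order. A simulated shift of a list of 20 genes by 1 on the log2 scale at day 7 was called in 50 of 50 simulations, and 2 of 1050 other list tests were called. Genes were simulated as independent of each other, so these counts do not give the rate of false list calls on the real arrays.

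The pool numbers were checked for pairing through the correlation of deviations from the group means between arrays of the same number. Only between NPd7 and NPd14 did all 3 same-numbered correlations pass 0.1 (0.16, 0.62 and 0.51 across probe sets). The numbers were therefore taken to pair NP pools across days, from the data and not from the labels. Pool 1 by itself gives no ground for this, as NPd7 pool 1 reached 0.19 with an NPd14 pool of another number. In the other 5 pairs of groups at least 1 correlation was 0.1 or less. Pools 2 and 3 also correlated by number between outcomes, at 0.36 and 0.27 for NPd7 with CDd7 and 0.33 and 0.25 for CDd7 with NPd14. Pool 1 had -0.03 in both, and NP pools with CDd14 pools had -0.26 to 0.16. Whether the number follows something other than heifers was not tested. The alternatives tried were no filter and a stricter filter (log2 above 6), other eBayes settings, only the groups of a contrast in the fit, median centring, quantile normalization, array weights, pool number as a block, other thresholds, the mean of all probe sets of a gene, and leaving out each array. After the data were seen, 3 were added: a score of stromal markers as a covariate, a score of the 3' to 5' signal of control transcripts as a covariate, and array weights by the gene-by-gene method. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.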

Results

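Gene expression was measured in endometrium collected by biopsy from heifers a cycle before they received an embryo. The 12 arrays fall into 4 groups of 3 pools: NPd7 and NPd14 from heifers that did not become pregnant, and CDd7 and CDd14 from heifers that delivered a calf. Array medians over all probe sets lay between 4.89 and 5.06 on the log2 scale, and 54.1% to 54.7% of probe sets were above the filter on each array. The correlation between arrays was 0.922 to 0.989 within groups and 0.862 to 0.981 between groups, across probe sets. The first principal component (45.4% of the variance) separated the days in CD, while NPd7 and NPd14 overlapped on it. The second (21.8%) was positive in NPd7 and NPd14 pool 3 and negative in CDd14.

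**Figure D1:**
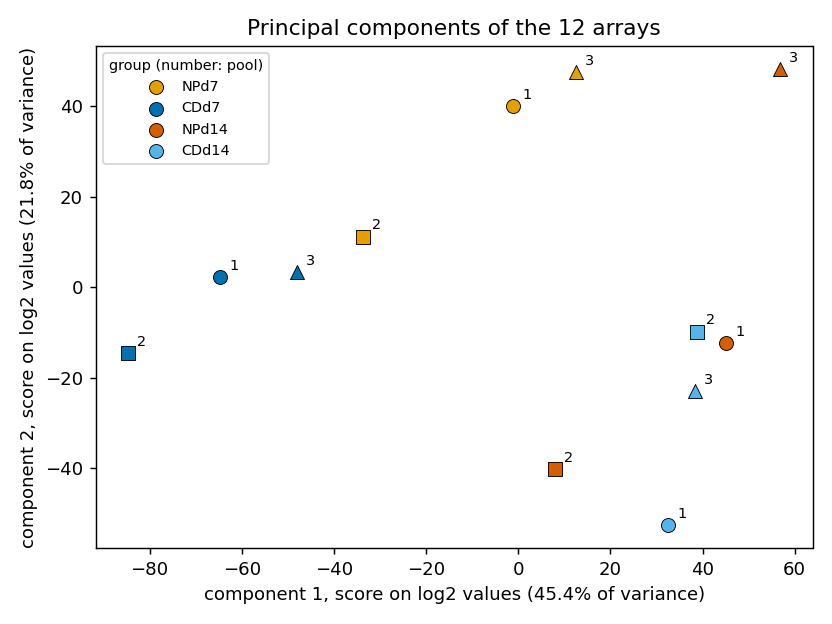
Scores of the 12 arrays on the first 2 principal components of the kept log2 values; each point is 1 array, colours are the groups and numbers the pools. The 3 CDd7 arrays lie at the lowest scores of component 1 (-84.6 to -48.0), the 3 CDd14 arrays lie between 32.5 and 38.8, and NPd7 pool 3 (12.5) lies above NPd14 pool 2 (8.07).

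A measure of RNA integrity and labelling moved with the groups. The mean difference between the 3' and 5' probe sets of the GAPDH, cyclophilin and EF1A control transcripts was 1.94 ± 0.19 in NPd7, 1.65 ± 0.20 in CDd7, 2.32 ± 0.17 in NPd14 and 1.97 ± 0.11 in CDd14 (log2, SD, n = 3). For 3 bacterial transcripts that are added to the sample, DAP, LYS and PHE, it was 5.06 ± 0.15, 4.74 ± 0.07, 5.38 ± 0.14 and 5.13 ± 0.12 in the same order. It was lower in CD than in NP on both days and higher at day 14 than at day 7 in both outcomes. The 8 exact permutation tests of these differences gave p = 0.1 to 0.3, where 0.1 is the smallest p that 3 against 3 arrays allow.

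The first comparison asks whether the endometrium of heifers that later delivered a calf already differed at day 7 of the preceding cycle. Transcripts of connective tissue were lower in CDd7 than in NPd7. SPARC, a collagen-binding matrix protein, fell from 8.59 ± 0.39 in NPd7 to 4.62 ± 0.47 in CDd7 (log2, SD, n = 3), 15.6-fold. The fibril collagen chains COL1A2 (9.20-fold) and COL3A1 (7.71-fold), the collagen-processing protein PCOLCE (7.01-fold) and the small proteoglycans OGN (11.4-fold) and LUM (8.25-fold) fell as well. CDK1, the mitotic kinase, rose 7.41-fold, from 6.92 ± 0.66 to 9.81 ± 1.44. CDC20, an activator of the anaphase-promoting complex, rose from 3.28 ± 1.07 to 7.79 ± 2.56, 22.7-fold from a mean under the filter, near background.

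Of 16 measured stromal fibroblast markers, 8 fell, 0 rose and 8 did not pass the threshold, with a median log2 fold change of -2.50, and 13 fell when adjusted over the list alone. Limma's camera gave an adjusted p = 6.99e-08 for the list (adjusted p = 0.868 with an estimated correlation). The 3' to 5' difference of the control transcripts was lower in the same group by 0.29, and by 0.32 for the added transcripts. T and natural killer cell markers were lower on all 14 measured genes (median -1.21), of which 3 fell: CD8A (3.23-fold) and CD8B (2.79-fold, to a level under the filter), the chains of the CD8 co-receptor, and LCK (2.44-fold), a kinase of T cell receptor signalling. The list's adjusted p was 0.000164 by camera (adjusted p = 0.891 with an estimated correlation), and 4 fell when adjusted over the list alone. Of 30 cell cycle genes, 4 rose and 26 did not pass (median 1.27, camera adjusted p = 5.43e-05, adjusted p = 0.897 with an estimated correlation, 7 adjusted over the list alone). Besides CDC20 and CDK1 these were CKS2 (3.63-fold), a subunit of cyclin-dependent kinases, and HMMR (2.46-fold), a spindle protein. Other kept probe sets of LCK, HMMR and COL1A2 had log2 fold changes of -0.63, 0.31 and -3.98 (limma adjusted p = 0.125, 0.190 and 0.0622). The cell cycle list was unevenly spread within CDd7, at -0.54 in pool 1 against 1.48 and 1.19 in pools 2 and 3 (mean deviation from all arrays, log2).

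Cytosolic ribosomal proteins were lower on all 58 measured genes by a small amount (median -0.24), of which 2 fell, RPS9 (1.46-fold) and RPL13 (1.55-fold), or 20 adjusted over the list alone (camera adjusted p = 1.65e-09, adjusted p = 0.891 with an estimated correlation). The lists of heat shock and the unfolded protein response (median 0.32, 1 rose of 29), of lipid synthesis and storage (median 0.49, 0 rose of 27) and of oxidative phosphorylation (median 0.36, 0 rose of 39) were higher in CDd7 by camera. Their adjusted p were 0.00788, 0.00503 and 0.000342, and adjusted p = 0.897, 0.905 and 0.906 with an estimated correlation. Adjusted over the list alone, 9 rose and 2 fell in the first, and 0 passed in the other lists. CALR, an endoplasmic reticulum chaperone, rose 2.09-fold, while PDIA3, a disulphide isomerase, and BAG3, a co-chaperone, had log2 fold changes of 0.55 ± 0.14 and 0.98 ± 0.26 (SE, limma adjusted p = 0.0532 and 0.0592). FABP5, a fatty acid carrier, had 1.45 ± 0.45 (limma adjusted p = 0.0764) and SDHB, a subunit of respiratory complex II, 0.49 ± 0.17 (limma adjusted p = 0.104).

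The list of 19 measured epithelial markers had a median of -0.03, with 0 past the threshold over all probe sets and 2 up and 2 down adjusted over the list alone. In lists that were not called, single genes passed: FGF2, a fibroblast growth factor, fell 2.86-fold, CFD, complement factor D, 2.63-fold, TIMP1, an inhibitor of matrix metalloproteinases, 3.13-fold, and MYC, a growth-related transcription factor, 2.53-fold. LRP5, a Wnt co-receptor, rose 1.81-fold. CLDN5, an endothelial tight junction protein and the 1 measured endothelial marker, rose 5.18-fold, and GYPC, a red cell membrane glycoprotein, fell 1.97-fold. Genes set in advance that did not pass had log2 fold changes of 0.08 ± 0.43 for OXTR, 2.86 ± 1.90 for MSTN, 1.31 ± 1.33 for SERPINA14, 1.86 ± 0.91 for LPL, 0.22 ± 0.64 for ISG15 and 0.28 ± 0.29 for MX1 (SE, limma adjusted p = 0.195 to 0.916). OXTR is the oxytocin receptor, MSTN myostatin, SERPINA14 the uterine milk protein and LPL lipoprotein lipase, while ISG15 and MX1 respond to interferon. Other genes with large rises were GCLC (11-fold, from a mean of 3.99 ± 0.96, near background), which makes the first intermediate of glutathione synthesis, and SPHK1 (5.30-fold), a sphingosine kinase. The junction protein GJA1 (9.98-fold), the myosin light chain kinase MYLK (9.40-fold) and HOXA9 (8.83-fold), a homeobox factor of the reproductive tract, fell. COL4A4 rose 9.85-fold and COL6A1 fell 11.4-fold, each from or to a level wholly under the filter, where a fold rests on values near background.

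In total 503 of 13449 probe sets changed at day 7 by limma with Benjamini-Hochberg adjustment, 242 up and 261 down, and of 6781 genes 99 rose and 137 fell. At an unadjusted p under 0.05 there were 4032 probe sets, against 672 by chance. In 35.3% of genes the 3 CDd7 and 3 NPd7 values did not overlap (10% by chance). The count was 0 without NPd7 pool 1 or pool 3 (2656 and 2347 at an unadjusted p under 0.05), 4 without CDd7 pool 2, 80, 158 and 224 without CDd14 pools 3, 1 and 2, and 196 without NPd14 pool 1. It was 909 without CDd7 pool 3, 1015 without NPd14 pool 2 and 1676 without NPd7 pool 2. Of 37 genes taken by the rule and past the threshold, some of them not named here, 0 passed in every one of these fits. It was 3 with only the 6 arrays of day 7 and 161 with no filter. It was 0 with the stromal score or the 3' to 5' score as a covariate, both chosen after seeing the data (336 and 1615 at an unadjusted p under 0.05). With these scores the median log2 fold change of the 503, each taken in the direction of its call, went from 1.06 to 0.78 and 0.92 and their median SE from 0.21 to 0.43 and 0.26.

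**Figure D2:**
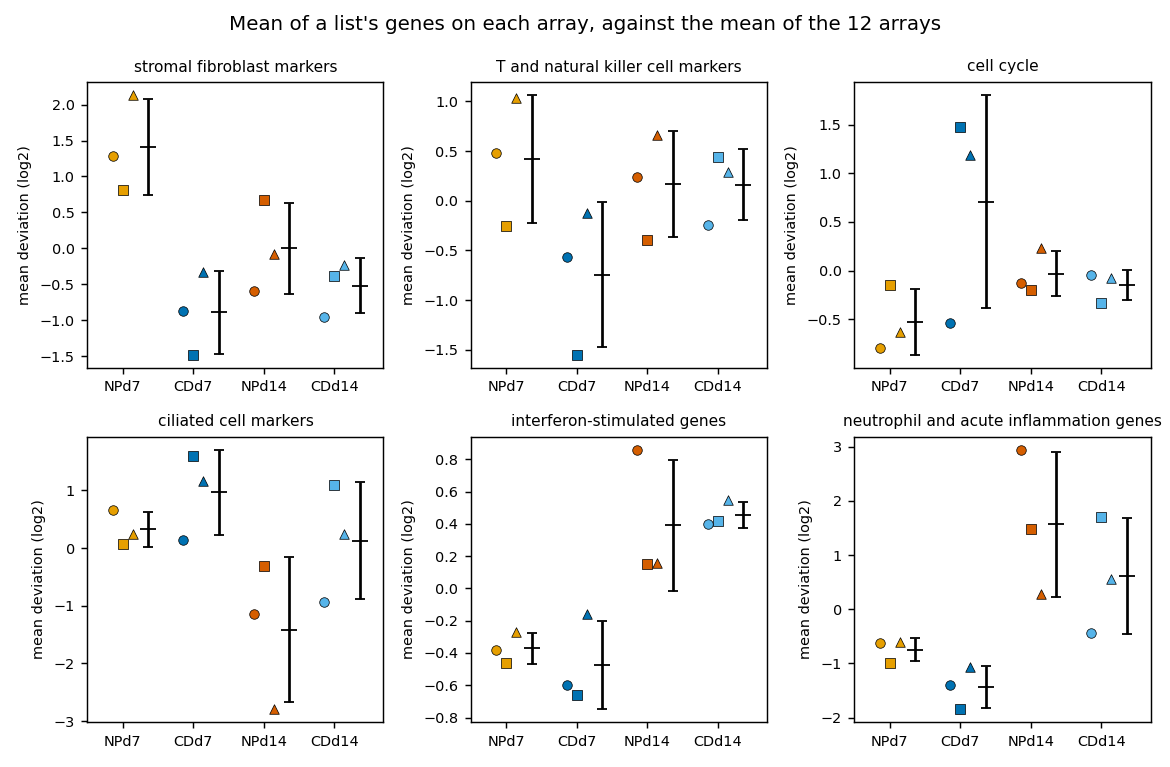
Mean over a list's measured genes of each gene's log2 deviation from its 12-array mean; each point is 1 array (circle, square and triangle for pools 1, 2 and 3), and bars show the group mean and SD (n = 3). Stromal fibroblast markers lie at 1.41 ± 0.67 in NPd7 and -0.89 ± 0.57 in CDd7, and interferon-stimulated genes are higher at day 14 than at day 7 in both outcomes.

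At day 14 the same question gave few differences. BRWD1, a bromodomain protein, fell from 7.68 ± 0.11 in NPd14 to 6.68 ± 0.07 in CDd14 (log2, SD, n = 3), 2-fold (limma adjusted p = 0.0236), while its other kept probe set had a log2 fold change of -0.41 (limma adjusted p = 0.782). A second probe set that passed, chosen here after its value was seen, is assigned to SLC25A12, a mitochondrial aspartate-glutamate carrier, and fell 2.83-fold, but the probe set that stands for this gene had a log2 fold change of 0.16 (limma adjusted p = 0.966). The remaining probe set that passed has no name in the annotation and fell 2.66-fold. The genes with the next smallest p did not pass: SLC52A3, a riboflavin transporter, had a log2 fold change of 3.24 ± 0.42 (SE, limma adjusted p = 0.0558), from a level under the filter in NPd14. SLC37A1, a sugar phosphate exchanger, had -0.93 ± 0.13 (limma adjusted p = 0.0771), GPALPP1 -0.88 ± 0.13 (limma adjusted p = 0.0870) and SFRS18 -1.03 ± 0.16 (limma adjusted p = 0.123).

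Ciliated cell markers were higher in CDd14 on all 8 measured genes (median 1.79), with 0 past the threshold singly or adjusted over the list alone (camera adjusted p = 4.95e-05, adjusted p = 0.891 with an estimated correlation). The list stood at -1.15, -0.32 and -2.79 in NPd14 pools 1 to 3 and at -0.94, 1.09 and 0.24 in CDd14 pools 1 to 3 (mean deviation from all arrays, log2), so NPd14 pool 3 carries much of the difference and CDd14 pool 1 lies within the range of NPd14. TEKT1, a protein of ciliary microtubules, had a log2 fold change of 1.88 ± 0.67 (SE, limma adjusted p = 0.575) and SPAG6, of the central apparatus of cilia, 1.95 ± 0.72 (limma adjusted p = 0.580). Neutrophil and acute inflammation genes (median -0.71 of 16), stromal fibroblast markers (median -0.50 of 16) and extracellular matrix turnover (median -0.28 of 15) were lower by camera, and oxidative phosphorylation was higher (median 0.15 of 39). Their camera adjusted p were 0.00137, 0.00463, 0.0354 and 0.0239, and adjusted p = 0.891, 0.897, 0.891 and 0.906 with an estimated correlation, with 0 genes past the threshold over all probe sets or adjusted over the list alone. S100A8, a calcium-binding protein of neutrophils, had -2.43 ± 1.07 (limma adjusted p = 0.674), SPARC -1.38 ± 0.80 (limma adjusted p = 0.767), PLAUR, the urokinase receptor, -0.79 ± 0.35 (limma adjusted p = 0.675) and NDUFB8, of respiratory complex I, 0.29 ± 0.13 (limma adjusted p = 0.671). The 3' to 5' difference of the control transcripts was lower in CDd14 by 0.35, and by 0.25 for the added transcripts. Genes set in advance had log2 fold changes of 0.50 ± 0.43 for OXTR, 2.32 ± 1.90 for MSTN, 3.29 ± 1.33 for SERPINA14, -2.49 ± 0.91 for LPL, -0.04 ± 0.64 for ISG15 and 0.56 ± 0.29 for MX1 (limma adjusted p = 0.576 to 0.997). Camera's call of the neutrophil list ended without NPd14 pool 1 (adjusted p = 0.166) or CDd14 pool 1 (0.199), that of the stromal list without NPd14 pool 2 (0.260) or CDd14 pool 1 (0.0985) and that of matrix turnover without NPd14 pool 2 (0.408) or CDd14 pool 3 (0.283). That of oxidative phosphorylation ended without NPd14 pool 3 (0.473), CDd14 pool 1 (0.558) or CDd14 pool 3 (0.127). With no filter the adjusted p was 0.0558 for the neutrophil list, 0.684 for matrix turnover and 0.0558 for oxidative phosphorylation, which also lost its call with quantile normalization (0.0652) and with the mean of a gene's probe sets (0.141).

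In total 3 probe sets changed at day 14, 0 up and 3 down (limma, Benjamini-Hochberg), with 993 at an unadjusted p under 0.05 against 672 by chance, and groups did not overlap in 10.6% of genes (10% by chance). The count was 0 under a stricter filter, trended and robust eBayes, the pool number as a block, the mean of the probe sets of a gene, only the arrays of day 14 or either covariate, and also without CDd7 pool 2, NPd14 pool 1 or 3 or CDd14 pool 3. It was 1 without NPd7 pool 1 or 2 or CDd14 pool 1, 5 without NPd7 pool 3 and 12 without NPd14 pool 2. Among the fits with a count of 0, 457 to 1155 probe sets or genes had an unadjusted p under 0.05 where it was counted. With the stromal and the 3' to 5' score the median log2 fold change of the 3 in the direction of the call went from 1.41 to 1.37 and 1.48 and their median SE from 0.16 to 0.18 and 0.22. Over all kept probe sets, the distance between arrays (1 minus Pearson's r) was larger between outcomes than within them by 0.0243 at day 7 (exact permutation test, p = 0.1, the smallest possible) and by 0.0013 at day 14 (p = 0.4).

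The third comparison sets the endometrium of heifers that delivered a calf at day 14 against that at day 7. Whether the pools of both days hold the same heifers is not given in the sources used here. The largest rise was in SLC39A2, a zinc transporter, from 3.93 ± 0.79 in CDd7 to 12.63 ± 0.51 in CDd14 (log2, SD, n = 3), 418-fold (limma adjusted p = 0.00852). The CDd7 mean lies under the filter, near background, as does that of the beta-defensin EBD (3.36 ± 0.63), which rose 160-fold. CXCL8, a chemokine that draws neutrophils, rose 91.5-fold and SERPINA14, the uterine milk protein, 41.5-fold. EDN3, the vasoactive peptide endothelin 3, fell from 11.80 ± 0.66 to 4.10 ± 0.15, 208-fold (limma adjusted p = 0.00702). LPL, lipoprotein lipase, fell 65.3-fold, PRODH, proline dehydrogenase, 78.9-fold, and the mitotic genes SPC24, of the kinetochore, and CCNB1, cyclin B1, 82.9-fold and 66.6-fold.

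Interferon-stimulated genes were higher: 16 of 26 rose and 0 fell (median 0.89), or 17 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000123, adjusted p = 0.891 with an estimated correlation). MX1, an antiviral GTPase, rose 2.81-fold, USP18, which removes ISG15 from proteins, 2.78-fold, PARP9 1.85-fold and ISG15, a ubiquitin-like modifier, 4.04-fold. Neutrophil and acute inflammation genes were higher (median 1.80, 5 rose of 16, likewise adjusted over the list alone, camera adjusted p = 0.00507, adjusted p = 0.891 with an estimated correlation). S100A12 rose 11.4-fold, CXCL2 4.84-fold and the interleukin 1 antagonist IL1RN 4.62-fold. Immediate early genes were higher (median 0.61, 5 rose and 1 fell of 16, likewise adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.891 with an estimated correlation). FOS (3.02-fold), ATF3 (4.54-fold) and MYC (2.62-fold) rose. Growth factors and their receptors were higher (median 0.91, 4 rose of 11, likewise adjusted over the list alone, camera adjusted p = 0.00788, adjusted p = 0.727 with an estimated correlation, fry adjusted p = 0.0149). IGFBP1, which binds insulin-like growth factors, rose 45.2-fold from a level under the filter, MET, the hepatocyte growth factor receptor, 5.01-fold, FGF2 3-fold and FGFR2 1.88-fold.

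Oxidative phosphorylation was lower, with 13 of 39 genes fallen, 0 risen and 13 adjusted over the list alone (median -0.45, camera adjusted p = 2.77e-05, adjusted p = 0.905 with an estimated correlation). ATP5MC1, of ATP synthase, fell 2.68-fold, SDHB 1.75-fold and NDUFC2, of complex I, 1.46-fold. T and natural killer cell markers were higher on all 14 genes (median 0.84, 2 rose or 1 adjusted over the list alone, camera adjusted p = 0.00788, adjusted p = 0.905 with an estimated correlation). CD69, an early activation marker, rose 4.73-fold and LCK 2.47-fold (0.53 on the log2 scale for its other kept probe set, limma adjusted p = 0.138). Without CDd7 pool 2 this list had a camera adjusted p = 0.0596. Ribosomal proteins were higher by a small amount (median 0.15, 1 rose of 58, RPL26, 1.33-fold, 0 adjusted over the list alone, camera adjusted p = 9.25e-05, adjusted p = 0.905 with an estimated correlation). The 3' to 5' difference of the control transcripts rose with these groups by 0.32, and by 0.39 for the added transcripts.

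The remaining lists were not called by camera between days in CD (adjusted p = 0.057 to 0.984), while members of them changed. For steroid and oxytocin receptors and partners, 2 rose and 1 fell of 7: NR3C1, the glucocorticoid receptor, rose 3.54-fold, PGRMC1, a progesterone receptor membrane component, 1.54-fold, and ESR2, an oestrogen receptor, fell 5.51-fold to a level under the filter. PGR, ESR1 and DKK1 did not pass the filter (highest log2 values 2.16, 1.63 and 2.06). OXTR, the oxytocin receptor, had a log2 fold change of 0.12 ± 0.43 (limma adjusted p = 0.864) and MSTN, myostatin, 2.21 ± 1.90 (limma adjusted p = 0.415). Among luteal-phase secretions 5 rose and 2 fell of 23 (6 and 3 adjusted over the list alone), including ANPEP, an aminopeptidase that fell 5.10-fold. Of 13 nutrient transporters 5 rose and 2 fell: the amino acid transporters SLC1A5 (up 1.79-fold) and SLC3A2 (down 1.60-fold) and the fatty acid transporter SLC27A6 (down 23.9-fold, to a mean under the filter). In prostaglandin genes 1 rose and 2 fell of 11: the receptors PTGER2 (up 3.49-fold) and PTGER4 (down 6.49-fold) and prostacyclin synthase PTGIS (down 5.21-fold). In the Wnt pathway 1 rose and 3 fell of 10, with TCF7L2, a transcription factor, up 4.01-fold and the ligand WNT11 down 14.5-fold.

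Of 30 cell cycle genes 1 rose and 6 fell, including CDC20 (16.3-fold, to a mean under the filter), HMMR (2.81-fold) and TK1, thymidine kinase (2.11-fold). The other kept probe set of HMMR had a log2 fold change of -0.30 (limma adjusted p = 0.169). Of 29 heat shock and unfolded protein response genes 2 rose and 10 fell, with the reticulum chaperone CANX down 1.56-fold, CRELD2 down 4.58-fold and BAG3 down 2.83-fold. Of 27 lipid genes 1 rose and 4 fell, with SREBF1, a regulator of fatty acid synthesis, down 2.96-fold, the elongase ELOVL5 down 2.06-fold and the scavenger receptor CD36 up 3.92-fold. In extracellular matrix turnover 3 rose and 4 fell of 15: PLAT, tissue plasminogen activator, rose 5.53-fold, TIMP3, a protease inhibitor, fell 15.2-fold to a level under the filter, and THBS1 fell 5.44-fold by its brightest probe set, while its 3 other kept probe sets had log2 fold changes of -2.27 (limma adjusted p = 0.00244), 0.14 (0.727) and 0.26 (0.709). Stromal markers had 2 up and 1 down of 16 (PDGFRA, a growth factor receptor, up 3.04-fold, and the protease MMP2, down 2.83-fold). Epithelial markers had 3 up of 19 (the secretory protein AGR2, 1.96-fold, and keratin KRT7, 1.99-fold, among them) and mucosal defence 3 up of 20 (PIGR, the polymeric immunoglobulin receptor, 2.52-fold). Antigen presentation had 2 up of 16, macrophage markers 1 up of 11 and ciliated cell markers 0 of 8. Adjusted over the list alone, the numbers up and down were 6 and 2 for nutrient transporters, 1 and 3 for prostaglandin genes, 5 and 4 for matrix turnover, 2 and 11 for heat shock, 1 and 3 for lipid genes, 1 and 1 for stromal markers and 1 and 0 for antigen presentation. They were the same as over all probe sets for receptors, the Wnt pathway, cell cycle, epithelial, mucosal, macrophage and ciliated cell lists. For matrix turnover the median was 0.39 and the mean -0.10. CLDN5 fell 22.2-fold to a level under the filter. Of the lists with too few measured genes for a test, B cell (3), mast cell (2), smooth muscle (3) and red cell (2) genes had 0 past the threshold.

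Between days in CD 3231 of 13449 probe sets changed, 1558 up and 1673 down (limma, Benjamini-Hochberg), and of the genes 669 rose and 964 fell. The groups did not overlap in 44.9% of genes (10% by chance). The count was 1320 without CDd7 pool 2, 1673 without CDd14 pool 3 and 2114 without CDd14 pool 2, and 174 with the 3' to 5' score and 2140 with the stromal score as a covariate. With these scores the median log2 fold change of the 3231, each taken in the direction of its call, went from 0.98 to 0.83 and 0.95 and their median SE from 0.23 to 0.28 and 0.24 (log2).

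**Figure D3:**
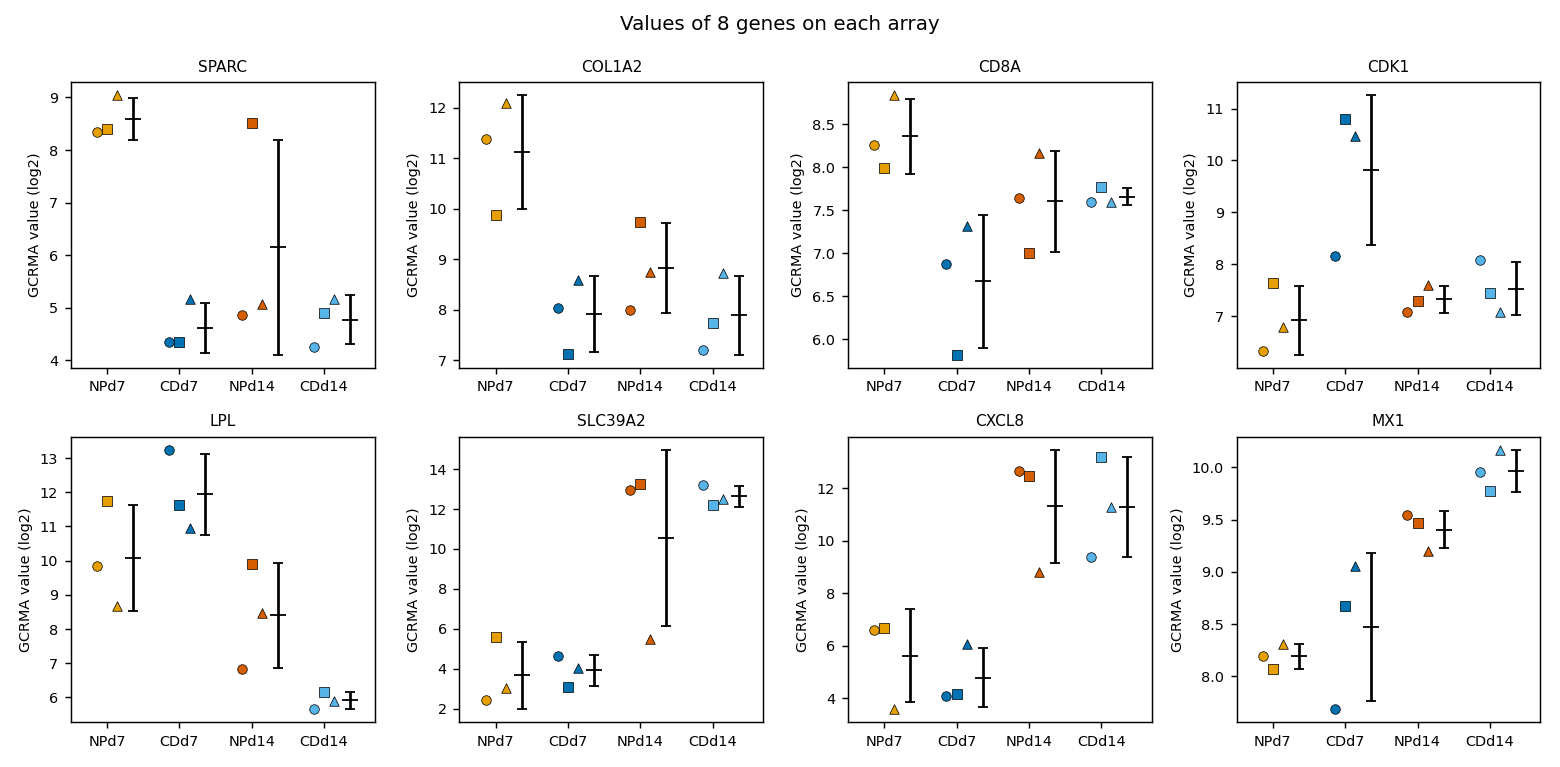
GCRMA log2 values of 8 genes on each array; circle, square and triangle are pools 1, 2 and 3, and bars show the group mean and SD (n = 3). SPARC and COL1A2 are higher in NPd7 than in CDd7, LPL is at 5.92 ± 0.25 in CDd14, and SLC39A2 lies at 5.49 in NPd14 pool 3 against 12.97 and 13.26 in pools 1 and 2.

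The same interval in heifers that did not become pregnant gave fewer calls. SLC7A1, a transporter of cationic amino acids, rose 2.01-fold, from 6.88 ± 0.16 in NPd7 to 7.89 ± 0.22 in NPd14 (log2, SD, n = 3, limma adjusted p = 0.0395). LARS2, the mitochondrial leucyl-tRNA synthetase, rose 3.36-fold, CCNL1, a cyclin linked to splicing, 2.23-fold and GPALPP1 2.12-fold from a level under the filter. CDK5, a kinase of the cyclin-dependent family, fell 2.15-fold, GNG11, a G protein subunit, 2.08-fold, PMF1, of the kinetochore, 1.88-fold, PAGR1 1.69-fold and AP4M1, of a vesicle coat adaptor, 1.58-fold. These calls come from the fit without pairing. With the pool number as a block, GPALPP1 and GNG11 passed (limma adjusted p = 0.0362 for both) and the other 7 genes had 0.0619 to 0.0746, and with a block within outcome 0 of the 9 passed (0.0621 to 0.0803).

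By camera 14 lists were called between days in NP. Interferon-stimulated genes were higher on 23 of 26 genes (median 0.65, camera adjusted p = 1.05e-08, adjusted p = 0.727 with an estimated correlation), with 0 past the threshold and 7 up adjusted over the list alone. MX1 had a log2 fold change of 1.21 ± 0.29 (limma adjusted p = 0.116), IFI27 2.50 ± 0.63 (limma adjusted p = 0.123) and ISG15 2.27 ± 0.64 (limma adjusted p = 0.158). Neutrophil and acute inflammation genes were higher on 15 of 16 (median 2.30, 3 up adjusted over the list alone, camera adjusted p = 5.80e-07, adjusted p = 0.868 with an estimated correlation), where CXCL8 had 5.70 ± 1.29 (limma adjusted p = 0.104) and CCL2, a monocyte chemokine, 3.60 ± 0.90 from a level under the filter (limma adjusted p = 0.123). Immediate early genes (median 0.30, camera adjusted p = 0.000234, adjusted p = 0.727 with an estimated correlation), growth factors (median 0.40, camera adjusted p = 0.0128, adjusted p = 0.727 with an estimated correlation) and cell cycle genes (median 0.48, camera adjusted p = 0.000305, adjusted p = 0.905 with an estimated correlation) were higher. FOS had a log2 fold change of 1.22 ± 0.23 (limma adjusted p = 0.0658). MET had 1.94 ± 0.41 (limma adjusted p = 0.0825). Adjusted over the list alone, these lists had 3, 2 and 0 up and 0, 1 and 0 down.

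Stromal fibroblast markers were lower (median -1.74, 8 of 16 down adjusted over the list alone, camera adjusted p = 0.00056, adjusted p = 0.891 with an estimated correlation). MMP2 was at -2.36 ± 0.43 (limma adjusted p = 0.0614). Ciliated cell markers were lower (median -2.17, 6 of 8 down adjusted over the list alone, camera adjusted p = 0.00958, adjusted p = 0.905 with an estimated correlation). TEKT1 was at -2.20 ± 0.67 (limma adjusted p = 0.171). Oxidative phosphorylation (median -0.27) and ribosomal proteins (median -0.09) were lower, and antigen presentation (median 0.35), mucosal defence (median 0.29), luteal-phase secretions (median 0.24), nutrient transporters (median 0.22) and lipid genes (median 0.09) were higher, with camera adjusted p = 0.000164, 0.0196, 0.0382, 0.0118, 0.0196, 0.0130 and 0.0406. With an estimated correlation these had adjusted p = 0.906, 0.906, 0.905, 0.891, 0.891, 0.891 and 0.906. Of these, nutrient transporters had 1 up over all probe sets and 3 adjusted over the list alone, mucosal defence 0 and 2, and the others 0 by either adjustment. DEFB4A, a beta-defensin, had 4.48 ± 0.93 (limma adjusted p = 0.0803), SPP1, osteopontin, 4.40 ± 1.14 (limma adjusted p = 0.135) and SLC1A5 0.78 ± 0.15 (limma adjusted p = 0.0731). SERPINA14 had 3.39 ± 1.33 from a level under the filter (limma adjusted p = 0.255), LPL -1.68 ± 0.91 (limma adjusted p = 0.386), MSTN 2.75 ± 1.90 (limma adjusted p = 0.504) and OXTR -0.30 ± 0.43 (limma adjusted p = 0.778). The 3' to 5' difference of the control transcripts was higher in NPd14 by 0.38, and by 0.32 for the added transcripts. Camera's calls of these lists ended with single arrays left out: luteal-phase secretions without NPd7 pool 1 (adjusted p = 0.0573), NPd7 pool 3 (0.0965) or NPd14 pool 2 (0.177). Nutrient transporters ended without NPd14 pool 2 (0.177), and antigen presentation without NPd7 pool 1 (0.0551), NPd7 pool 2 (0.0695) or NPd14 pool 1 (0.716). Mucosal defence ended without NPd7 pool 3 (0.0559), ciliated cell markers without NPd14 pool 3 (0.0587), oxidative phosphorylation without NPd7 pool 2 (0.0643) or NPd14 pool 3 (0.159) and ribosomal proteins without NPd7 pool 3 (0.327) or NPd14 pool 2 (0.818) or with quantile normalization (0.140). Lipid genes ended without NPd7 pool 1 (0.126), NPd7 pool 3 (0.446), CDd7 pool 3 (0.0530), NPd14 pool 1 (0.0865) or NPd14 pool 2 (0.546).

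In total 44 probe sets changed between days in NP, 37 up and 7 down (limma, Benjamini-Hochberg), with 2196 at an unadjusted p under 0.05, and the groups did not overlap in 22.6% of genes (10% by chance). With the pool number as a block shared by all 12 arrays, which also ties CD pools to NP pools by number, 21 probe sets passed (18 of the 44). With a block within outcome, which pairs NP pools across days apart from CD pools, 0 did (2685 at an unadjusted p under 0.05). The count was 1 without NPd7 pool 1, 9 without NPd14 pool 1, 155 without NPd14 pool 2 172 without NPd14 pool 3, and 22, 13, 19, 22, 17, 17, 24 and 21 without NPd7 pools 2 and 3, CDd7 pools 1 to 3 and CDd14 pools 1 to 3. It was 0 with only the NP arrays in the fit and 0 with the stromal or the 3' to 5' score as a covariate (1015 and 963 at an unadjusted p under 0.05), where the median log2 fold change of the 44 in the direction of the call went from 1.22 to 1.28 and 1.13 and their median SE from 0.19 to 0.27 and 0.24.

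The difference of the day effects tests whether the course from day 7 to day 14 differed between outcomes. The same contrast tests whether the difference between outcomes changed from day 7 to day 14. The counts of 503 probe sets at day 7 and 3 at day 14 are not such a test. The genes with the smallest p were FGFBP1, which releases fibroblast growth factors from the matrix, with a difference of 2.46 ± 0.39 on the log2 scale (CD minus NP, SE), FGF2 with 2.80 ± 0.49, SLC52A3 with 3.31 ± 0.60, TFDP2, a partner of E2F factors, with -1.83 ± 0.30 and SEPTIN4, a cytoskeletal GTPase, with -2.55 ± 0.46 (limma adjusted p = 0.192 for each). By itself FGF2 rose between days in CD and had a log2 fold change of -1.21 ± 0.35 in NP (limma adjusted p = 0.163). By limma 0 of 13449 probe sets passed, with 1900 at an unadjusted p under 0.05 against 672 by chance, 0 with trended and robust eBayes (1989 unadjusted), 1 with no filter, 28 with a block within outcome and 503 with gene-by-gene array weights. Leaving out 1 array gave 53 without NPd7 pool 2, 22 without CDd7 pool 1, 5 without CDd7 pool 3, 3 without CDd14 pool 2 and 0 otherwise.

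Across 6781 genes, which are not independent replicates, the day effects in CD and NP had Pearson's r = 0.654 and Spearman's rho = 0.537, and 67.9% had the same sign. The arrays behind the 2 effects are separate, but both effects went with a rise of the 3' to 5' difference. It rose by 0.32 in CD and 0.38 in NP, and by 0.39 and 0.32 for the added transcripts. A shift shared with that measure was therefore not told apart from a shared course. Of 1633 genes called in CD, 1444 (88.4%) had the same sign in NP, with a median ratio of the NP to the CD effect of 0.357. These genes were picked by their effect in CD, which by itself lowers that ratio, so it does not measure the size of the NP course. In the fit without pairing, of the 4 genes that rose in NP, 3 also rose in CD (0.395 if the calls were independent). Of 5 that fell, 4 also fell (0.711 if independent). The calls share 1 estimate of spread per probe set, so they are not independent and these expected numbers need not hold.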

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

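The tests of the position along the course from day 7 to day 14, of the stromal markers on that course, of the start of NPd7 and of the spread among NP pools were chosen only after the result was seen. Each list difference below was picked out because the day effect differed between CD and NP by limma's camera at the preset correlation, as median log2 difference of CD minus NP. Stromal fibroblast markers had 2.11 (camera adjusted p = 4.95e-05, adjusted p = 0.891 with an estimated correlation) and T and natural killer cell markers 1.29 (0.000448, adjusted p = 0.897 with an estimated correlation). Cell cycle genes had -1.35 (2.20e-06, adjusted p = 0.891 with an estimated correlation) and heat shock and unfolded protein response genes -0.30 (0.00348, adjusted p = 0.891 with an estimated correlation). Lipid genes had -0.41 (0.000527, adjusted p = 0.905 with an estimated correlation) and ribosomal proteins 0.28 (1.65e-09, adjusted p = 0.891 with an estimated correlation). Oxidative phosphorylation had -0.18 (0.0436, adjusted p = 0.906 with an estimated correlation), and its call ended without NPd7 pool 1 (0.141) or 3 (0.181), CDd7 pool 2 (0.238), NPd14 pool 1 (0.206) or 2 (0.408) or CDd14 pool 2 (0.420), with quantile normalization (0.0761) and with the mean of a gene's probe sets (0.0542). The stromal score was 1.41 ± 0.67 in NPd7, -0.89 ± 0.57 in CDd7, 0.00 ± 0.64 in NPd14 and -0.52 ± 0.38 in CDd14 (SD, n = 3), so NPd7 was higher than CDd7 by more than NPd14 was higher than CDd14.

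Regrouping the samples shows how often other splits give as much. The splits took no account of the pool numbers, so the pairing taken for NP pools across days was not kept in them. For the difference of the day effects, 37 of 100 splits called at least the 7 lists of the real split (highest other 13), so chance is not excluded for the lists. For probe sets the real count was 0 by limma (1900 at an unadjusted p under 0.05), which any of the 100 splits reaches whatever the data, so the splits say nothing about it. The highest other count was 207, and what the arrays grouped in that split share was not tested. The pairwise comparisons have 10 splits each, the real one included, too few for a share under 0.05, so they cannot exclude chance. For probe sets, 1 split reached the real 503 at day 7 (highest other 5), 3 reached the real 3 at day 14 (highest other 5), 1 reached the real 3231 between days in CD (highest other 1) and 1 reached the real 44 between days in NP (highest other 13). For lists, 3 splits reached the real 7 at day 7 (highest other 10), 10 reached the real 5 at day 14 (highest other 10), 5 reached the real 7 in CD (highest other 10) and 1 reached the real 14 in NP (highest other 12). At day 7, at day 14 and in CD, other splits thus called as many lists as the real one. Regrouping did as well there, so the number of lists called does not speak for a difference between the groups. The same holds for the 3 probe sets at day 14.

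The 503 probe sets that differed at day 7 may follow the amount of connective tissue in the biopsies, RNA integrity or labelling, the stage of the cycle, or a difference between heifers by outcome, which stays open and was not tested apart from these. The 3 measured smooth muscle markers, MYLK among them, were also higher in NPd7 (0.86 ± 0.22) than in CDd7 (-0.35 ± 0.20, mean deviation from all arrays, log2, SD, n = 3). That list was too short for a set test, and the share of muscle in the biopsies was not tested. The slope on the stromal score within groups gave a median share of 0.249 of the log2 fold change for the 494 probe sets outside the stromal list (0.0899 to 0.529 over fits without 1 array). For the 3' to 5' score it was 0.132 (0.0456 to 0.308). A lowest of these fits at 0.5 or more would have spoken for an explanation and a highest under 0.25 against it, and as neither score met either bound both stay open. The added bacterial transcripts share the 3' to 5' difference at day 7 (-0.32 against -0.29 for the tissue transcripts). For them CDd7 arrays lay at 4.66 to 4.79 and NPd7 arrays at 4.96 to 5.23. These transcripts do not come from the tissue, so their shift is not one of tissue RNA integrity. A difference in labelling or array processing cannot be told apart from outcome at day 7. On the axis from CDd7 to CDd14 the NPd7 pools lay at 0.461 ± 0.166 and the left-out CDd7 pools at 0.069 ± 0.203 (SD, n = 3), and the lowest NPd7 pool exceeded the highest CDd7 pool by 0.012, far less than either SD, so a later stage of the NPd7 pools stays open for the probe sets as a whole. For the stromal markers it is argued against, since the lowest NPd7 score exceeded the highest score of the CD arrays of both days by 1.04 (log2), unless these markers pass through a peak between the days, when no arrays were taken.

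That 44 probe sets passed between days in NP against 3231 in CD could come from spread among the NP pools or from smaller changes. The test of the difference of the day effects called 0 of 13449 probe sets (limma, smallest adjusted p = 0.192). The counts by themselves therefore do not show that the day effects differ. With the spread between arrays taken off, the SD of log2 fold changes was 0.41 in NP and 0.863 in CD. The ratio was 0.475 (0 to 0.611 without 1 array, taking a negative variance as 0). This argues against larger spread alone, for which at least 0.8 was required. The spread taken off treats arrays as unpaired, and if NP pools pair across days it takes off too much and lowers the ratio. Before it was taken off, the SD across genes was 0.563 in NP and 0.895 in CD, also smaller in NP. On the CD axis the step from day 7 to day 14 was 0.390 in NP and 0.834 in CD. The start of NPd7 past CDd7 made up 0.884 of that shortfall (0.734 to 0.989 over the axes). At least 0.8 was required even in the lowest axis, where it was 0.734, so a later start in NPd7 stays open. The axis was built from CD arrays, and a course of another kind in NP would also shorten the NP step on it.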

How the results depend on the processing

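The covariates and the gene-by-gene array weights were chosen after seeing the data. Counts are of probe sets. At day 7 there were 161 with no filter, 1455 with pool number as a block, 0 with the stromal score and 0 with the 3' to 5' score as a covariate, 3 with only the groups compared, 279 with a fold of 2 added, 2262 at an adjusted p under 0.1 and 1124 at an unadjusted p under 0.05 with a fold of 2. At day 14 these were 6, 0, 0, 0, 0, 3, 7 and 240, with 0 under the stricter filter, 0 with trended and robust eBayes and 1 with quantile normalization. Between days in CD, 2140 (stromal score), 174 (3' to 5' score), 1575 (fold of 2) and 1928 (unadjusted p and fold) lay outside 1.5 times the count. Between days in NP there were 9 under the stricter filter, 17 with trended and robust eBayes, 21 with the block, 0 with the block within outcome, 0 with either covariate, 0 with only the groups compared, 156 at an adjusted p under 0.1 and 580 at an unadjusted p with fold. For the difference, 1 (no filter), 28 (block within outcome) and 817 (unadjusted p and fold) differed from 0. With the mean of a gene's probe sets the counts are of genes and compare with genes: 307 against 236 at day 7, 0 against 1 at day 14, 1674 against 1633 in CD and 2 against 9 in NP. The default array weights gave 4027, 3515, 5033, 5559 and 2825 in the order day 7, day 14, CD, NP and difference, but their estimation stopped before it converged and gave NPd14 pool 1 a weight of 44 against 0.277 for the lowest. The gene-by-gene weights (0.379 to 4.13) gave 3645, 311, 4478, 2499 and 503. Camera with an estimated correlation called 0 lists (6 at an unadjusted p under 0.05) and fry 1. Fewer arrays enter the fit of only the groups compared; otherwise the cause was not tested.

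Leaving out 1 array gave 0 (without NPd7 pool 1 or 3) to 1676 (NPd7 pool 2) at day 7, 0 (CDd7 pool 2, NPd14 pool 1 or 3, CDd14 pool 3) to 12 (NPd14 pool 2) at day 14, 1320 (CDd7 pool 2) to 3732 (NPd14 pool 3) in CD, 1 (NPd7 pool 1) to 172 (NPd14 pool 3) in NP and 0 to 53 (NPd7 pool 2) for the difference. Lists called were 35 to 42, and the correlation of day effects was 0.474 to 0.725. The genes taken by the rule and past the threshold include some at day 7 that the text does not name. Of them, 7 of 37 at day 7, 0 of 1 at day 14, 52 of 69 in CD and 1 of 9 in NP passed under all of 5 other settings. These settings were no filter, trended and robust eBayes, quantile normalization, block and mean per gene. In every fit without 1 array 0, 0, 39 and 0 passed, in the same order. In these fits 0 of the genes past the threshold changed sign. Genes not past it changed sign without single arrays: OXTR (-0.23 to 0.49), ISG15 (-0.46 to 0.72) and MX1 (-0.01 to 0.67) at day 7, ISG15 at day 14 (-0.50 to 0.63) and OXTR in CD (-0.21 to 0.43) and NP (-0.68 to 0.10). Signal near background limits folds of dim genes.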

Other observations

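The genes with the largest changes between days in CD included some not described above. PLET1, a membrane protein found in placenta, rose 131-fold (log2 fold change of 4.12 for its other kept probe set, limma adjusted p = 0.0705), GPLD1, which cleaves glycosylphosphatidylinositol anchors, 91.3-fold, HCRTR1, an orexin receptor, 36.5-fold and SLC16A1, a lactate and pyruvate transporter, 32.8-fold, each from a level under the filter in CDd7, where a fold rests on values near background. UNC45B, a myosin chaperone, rose 40.5-fold. BSP3, of a family of sperm-binding proteins, fell 102-fold and ADAMTS6, a metalloprotease, 38.6-fold, both to a level under the filter in CDd14. PDZK1, a scaffold of membrane transporters, fell 74.7-fold from 13.60 ± 0.30 to 7.38 ± 1.80 (log2, SD, n = 3), SUSD2, a membrane protein, 52.7-fold and DAPL1 53.3-fold (limma adjusted p = 0.00176 to 0.0437 for these 10 genes).

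The 3 measured B and plasma cell markers, JCHAIN and IGHM, chains of immunoglobulin, and DERL3, of protein degradation at the endoplasmic reticulum, had mean deviations of 0.57 ± 0.59 in NPd7, -1.03 ± 0.93 in CDd7, 0.99 ± 1.34 in NPd14 and -0.53 ± 0.44 in CDd14 (log2, SD, n = 3). All 3 were lower in CD on both days, with medians of -0.96 at day 7 and -0.81 at day 14, and 0 passed by limma on either day. This list was too short for a set test. Ciliated cell markers were at 0.33 ± 0.30 in NPd7, 0.97 ± 0.75 in CDd7, -1.42 ± 1.26 in NPd14 and 0.13 ± 1.02 in CDd14.

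The tests in this paragraph were chosen only after the result was seen. NPd14 pool 3 stood apart from NPd14 pools 1 and 2 on component 2 (48.3 against -12.3 and -40.1), with SLC39A2 at 5.49 against 12.97 and 13.26 and CXCL8 at 8.83 against 12.68 and 12.46 (log2). Pool 2 differed from its group almost as much (mean r with its group 0.946, against 0.941 for pool 3), and it was the array apart on component 1 (8.07 against 45.2 and 56.8), on the CD axis (0.712 against 0.934 and 0.907) and for SPARC (8.51 against 4.87 and 5.08). The position of pool 3 on the CD axis lay past the midpoint between NPd7 and the other NPd14 pools by 0.265 (0.222 to 0.316). Over the probe sets as a whole this argues against a wrong day label, although SLC39A2 lies among the day 7 values (2.42 to 5.58). Luteal-phase secretions were at -0.96 in pool 3 and -0.91 to -0.03 in NPd7, and nutrient transporters at -0.74 and -0.68 to -0.16 (mean deviation from all arrays, log2). For these lists pool 3 thus stood at the day 7 level. Interferon-stimulated genes (0.16) and neutrophil genes (0.28) in pool 3 lay above NPd7 (-0.46 to -0.27 and -0.99 to -0.61). The 3' to 5' score of pool 3 was outside the range of the other pools by 0.01, against a range of 0.29, which argues against RNA integrity or labelling as measured there. Its deviations correlated with those of NPd7 pool 3 at r = 0.51 across probe sets (0.62 between the pools numbered 2). For NP pools of different numbers the highest was 0.19, though deviations in a group sum to 0, which by itself lowers these. A trait shared by heifers of NP pool 3 on both days may account for how pool 3 stood apart, as a hypothesis. CDd7 pool 3, of the other outcome, also correlated with NPd7 pool 3 (0.27) and NPd14 pool 3 (0.25), while CDd14 pool 3 had 0.05 and 0.16. Something else that follows the pool number was not told apart from such a trait.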
